A study of Mus musculus with 6 samples.

How the data were processed

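RNA was sequenced from 6 primary cancer cell lines cultured from tumours of C57BL/6 mice, 3 from hosts labelled WT and 3 from hosts labelled Rag1KO. According to the labels, tumours were minced, digested with collagenase and dispase and then trypsin, and the cells were grown in DMEM with serum before RNA was extracted with RNeasy columns and libraries were made with Illumina's TruSeq Stranded kit. The submitters' notes name Trim Galore 0.6.6, FastQC, STAR 2.7.9a, DESeq2 and the mm10 genome build without saying what each was used for. The read counter and the gene annotation were not stated, nor were the tumour type and the hosts' sex.

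The deposited files hold 1 signal value per gene and library, for 55401 genes. The values themselves show how the authors scaled them: each is a whole number of reads divided by 1 size factor per library, all values being whole within 0.01 reads after multiplication. The factors equal median-of-ratios factors computed over the 6 libraries, with a largest relative difference of 1.03e-10. Libraries held 55409583 to 62998051 reads. A count of 0 was taken to allow up to 3 reads, or 2.64 to 3.48 normalized counts depending on the library, and such limits cover counting error only. Gene IDs were matched to GENCODE M21, where 55141 were found, 54349 of them in the same version. Coordinates are from that annotation.

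Groups followed the labels, and replicate numbers were not shared between the groups. The tests, gene lists, threshold and rule for naming genes were chosen before the data were examined. The planned test for read counts was edgeR's quasi-likelihood test, to be replaced by limma if the files held normalized values, which they did. Genes were kept by edgeR's filterByExpr on the recovered reads, leaving 16137. limma 3.58.1 was fitted to log2(value + 1) with a mean-variance trend, the contrast being WT minus Rag1KO, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Intervals are at 95%.

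Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 27 lists with at least 5 tested members. They covered metabolism (glycolysis, nuclear-encoded and mitochondrially encoded respiratory chain, TCA cycle, pentose phosphate and nucleotide synthesis, serine and one-carbon metabolism, amino acid transport and glutamine metabolism, cholesterol and fatty acid synthesis, fatty acid oxidation) and immune functions (interferon response, MHC class I and II antigen presentation, immune checkpoint and ligand genes, chemokines and cytokines). Others covered signalling and cell state (MYC targets, JAK-STAT3, hypoxia, proliferation, p53 targets and cell cycle inhibitors, unfolded protein and integrated stress response, extracellular matrix and mesenchymal genes, chromatin and DNA methylation enzymes). Marker lists covered melanocytes, neural crest and Schwann cells, fibroblasts, pericytes and smooth muscle, endothelium, epithelium and keratinocytes, leukocytes and macrophages, and lymphocytes. A sex-linked list (Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty) and a list of genes fixed by name were not tested as sets. Principal components were computed from log2 CPM with a prior count of 2.

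Named genes are up to 10 per direction past the threshold with separated groups and a mean log2 CPM of at least 1, filled up to 5 per direction by the lowest p. Predicted gene models and the genes of the sex-linked list were left out of that part. Up to 4 genes of the lowest p in each list, the fixed genes and the sex-linked genes were added, and any other gene is said to have been chosen after its values were seen.

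Alternatives were edgeR 4.0.16 (TMM and RLE), DESeq2 1.42.0 and limma-voom with and without sample weights, all on the recovered reads. Others were TMM, upper-quartile and library-size scaling, no filter, a filter of 1 CPM in 3 libraries, a pseudocount of 0.1 and thinning to the smallest library. Leaving out each library, leaving out the sex-linked list and mitochondrially encoded genes, and inferred sex as a covariate were tried too. For lists, an estimated correlation and fry were tried. The edgeR TMM test, planned as the main test for read counts, was added as an alternative after the data were seen. So were TMM scaling, the pseudocount for lists and combinations that leave out WT replicate 6. The estimated correlation and the components with a library left out were also added then. Calculations used R 4.3.3, and figures Python 3.11.15 with matplotlib 3.10.9. limma and edgeR were tested on simulated data: at the spread of the real libraries limma called 218 genes over 3 draws, 21 of them false, and edgeR 185, 10 of them false.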

Results

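RNA sequencing was carried out on 6 mouse primary cancer cell lines, each cultured from a tumour that had grown in a C57BL/6 host. The hosts of 3 lines were labelled WT (replicates 2, 4 and 6) and those of the other 3 lines were labelled Rag1KO (replicates 1, 3 and 7). Rag1 encodes a subunit of the recombinase that assembles antigen receptor genes, and mice without it make no mature T or B cells. The comparison therefore asks how cancer cells that had grown under an adaptive immune system differed from cells that had grown without it, with metabolism and immune evasion as the themes in the series' title. Each library held between 55409583 and 62998051 reads assigned to genes, and the values below are read counts divided by 1 size factor per library, here called normalized counts. The labels name separate lines without saying that each came from its own animal, so p-values measure the spread between these samples. Levels are given as the mean ± SD of normalized counts (n = 3), lines labelled WT first and lines labelled Rag1KO second. Folds come from means on the log2 scale. Against a group without reads, an "at least" fold is instead the other group's mean of normalized counts over the mean limit allowed for no reads.

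Rag1 itself was detected in the lines labelled Rag1KO and not in those labelled WT. Rag1 (ENSMUSG00000061311.6, chromosome 2, 101638282 to 101649501, mm10) reached 39.3, 126 and 177 normalized counts in Rag1KO replicates 1, 3 and 7, from 41, 109 and 183 reads. The 3 libraries labelled WT held 0 Rag1 reads, so the mean in the lines labelled Rag1KO was at least 40.1-fold higher, taking 3 reads in each library as the limit that a count of 0 allows. Rag2, the neighbouring gene for the recombinase's partner subunit, had 0 reads in all 6 libraries. The adjusted p for Rag1 was 0.338 by limma over all genes tested and 0.000883 adjusted over the list alone, the list being the genes fixed by name beforehand. It was 0.891 by edgeR and 1.85e-06 by DESeq2. Counts per gene do not show which part of Rag1 the reads cover and so do not show an intact transcript. A gene simply lost would give no reads in the lines labelled Rag1KO, where reads were found, so groups are named by their labels throughout.

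**Figure D1:**
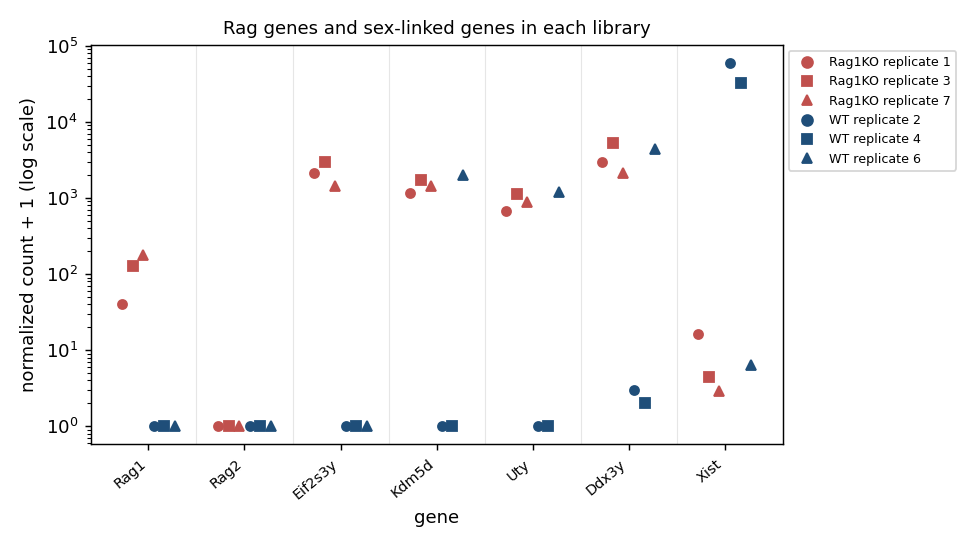
Normalized counts plus 1, on a log axis, of Rag1, Rag2, 4 Y-linked genes and Xist, with 1 point per library, coloured by the labelled host group. Rag1 lies between 39.3 and 177 normalized counts in the 3 lines labelled Rag1KO and at 0 in the 3 labelled WT, and Eif2s3y is at 0 in all 3 lines labelled WT although replicate 6 has the other Y-linked genes.

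Sex-linked genes differed between the lines. The Y-linked genes Eif2s3y, Kdm5d, Uty and Ddx3y were expressed in all 3 lines labelled Rag1KO, where Xist, the RNA that silences an X chromosome in female cells, stayed at or below 15.3 normalized counts. WT replicates 2 and 4 showed the opposite, with Xist at 59776 and 32733 normalized counts and at most 2 reads of any of the Y-linked genes. WT replicate 6 had 5.3 normalized counts of Xist and expressed Kdm5d at 1994, Uty at 1196 and Ddx3y at 4345 normalized counts, but had 0 reads of Eif2s3y. The hosts' sex was not in the labels. With WT replicate 6 left out, as in many checks below, WT replicates 2 and 4 are compared with lines that all express Y-linked genes. Those fits cannot tell an effect of the host label from this sex-linked difference. With all 6 libraries the 2 still largely coincide, since WT replicate 6 was the only line labelled WT that expressed Y-linked genes.

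Between the groups, 1 of 16137 genes passed the threshold in limma, and it was Y-linked. Eif2s3y (chromosome Y, 1010543 to 1028847), which encodes a subunit of translation initiation factor eIF2, had 2164 ± 755 normalized counts (SD, n = 3) in lines labelled Rag1KO and 0 reads in those labelled WT, at least 759-fold lower. Its log2 fold change (WT minus Rag1KO, on the log2(value + 1) scale) was −11.02 with an SE of 0.45 and an adjusted p of 0.00525. The sex-linked list gave 1 call adjusted over the list alone, the same gene. With any single library other than WT replicate 6 left out, limma called 0 genes. Without WT replicate 6 it called 5, all sex-linked: Kdm5d, Eif2s3y, Uty, Ddx3y and Xist.

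Next come the 5 genes per direction with the lowest p. They were taken from genes with a mean log2 CPM of at least 1 whose groups did not overlap, a choice that leaves out the weakly expressed Rag1. Predicted models and the genes of the sex-linked list were left out, but no other genes of the sex chromosomes. None of the genes so chosen passed limma's threshold. Arhgdib, a gene abundantly expressed in blood cells, had 29929.6 ± 5786 normalized counts against 4662 ± 1539 (6.55-fold, log2 fold change 2.71, SE 0.29, adjusted p 0.338). Mgp, which encodes matrix Gla protein and lies near it on chromosome 6 (Mgp at 136872435 to 136875823, Arhgdib at 136923655 to 136941899), had 10619.8 ± 8990.5 normalized counts against 825 ± 591. Acpp, an acid phosphatase gene, averaged 1422 ± 342 normalized counts against 101 ± 67.1. Vdac2, a channel of the outer mitochondrial membrane, was at 14592 ± 452 normalized counts against 8596 ± 967, a ratio of 1.7. Lclat1, a lysophospholipid acyltransferase that acts on cardiolipin, was at 6345 ± 777 normalized counts against 3695 ± 91.6. On the other side, 5 genes were higher in lines labelled Rag1KO. The anion exchanger gene Slc4a3 had 829 ± 185 normalized counts against 2082 ± 258, and Pros1, encoding protein S, a ligand of TAM receptors, had 2147 ± 327 normalized counts against 4529 ± 684. Efr3b, Mid1 and Dlc1 were 8.2-fold, 2.02-fold and 2.32-fold higher in lines labelled Rag1KO. Apart from Arhgdib, the adjusted p in limma was 0.85 for each of these genes. Mgp went from 3.62 to 2.97 on the log2 scale without WT replicate 6.

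**Figure D2:**
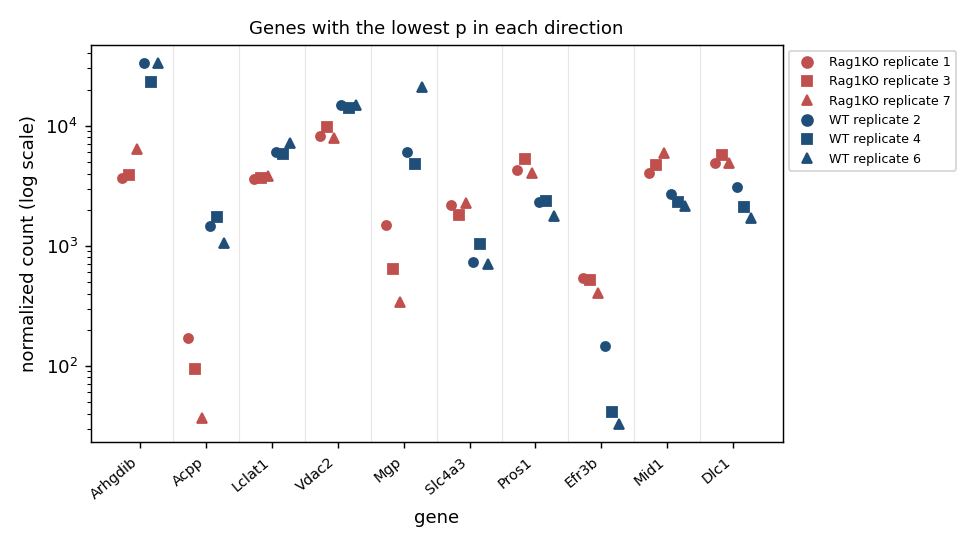
Normalized counts, on a log axis, of the 5 genes with the lowest p in each direction, with 1 point per library. Genes had a mean log2 CPM of at least 1 and separated groups, and predicted models and the sex-linked list were left out. Arhgdib, Acpp, Lclat1, Vdac2 and Mgp lie higher in the 3 lines labelled WT, Slc4a3, Pros1, Efr3b, Mid1 and Dlc1 higher in the 3 labelled Rag1KO, and none of the 10 passed the adjusted threshold in limma.

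The number of calls depended on the test. At an unadjusted p under 0.05, limma gave 754 genes where chance gives 807, and edgeR's quasi-likelihood test on the recovered reads gave 717 and called 0 genes at its adjusted threshold. DESeq2, the tool named in the submitters' processing notes, gave 1055 where chance gives 793, and at its adjusted threshold called 65 genes, 20 of them higher in lines labelled WT and 45 higher in lines labelled Rag1KO. These 65 included Rag1, Eif2s3y, Xist and, of the 10 genes above, all but Dlc1, whose adjusted p there was 0.071. Genes whose groups did not overlap numbered 1951, or 12.1% of those tested, where chance gives 10%. The median SE of a log2 fold change was 0.40, and the median 95% interval reached 1.97-fold to either side. In simulated data with the spread of these libraries, limma recovered 0% of 2-fold, 16% of 4-fold, 45.3% of 8-fold and 70% of 16-fold changes. In that simulation 2-fold differences of single genes were therefore not detectable by limma. Genes were drawn independently, with the spread estimated over all libraries including WT replicate 6, and only more highly expressed genes were changed. A single library shifting many genes together was not simulated.

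None of the genes fixed by name for metabolism, MYC and interferon signalling passed the threshold, their adjusted p lying between 0.85 and 0.919. Myc had 5179 ± 2016 normalized counts against 3551 ± 329.9, the glucose transporter gene Slc2a1 6958 ± 3186 normalized counts against 4522 ± 1441, the lactate dehydrogenase gene Ldha 37254 ± 3305 normalized counts against 31952 ± 6895 and the hexokinase gene Hk2 2447 ± 874 normalized counts against 1969.7 ± 823. For the interferon gamma receptor, Ifngr2 had 2989 ± 609.8 normalized counts against 4139 ± 139 and Ifngr1 3329 ± 1092 normalized counts against 4506 ± 619.8. Stat3 had 8047 ± 4459 normalized counts against 11201 ± 4456. B2m, the light chain of MHC class I, had 43906 ± 35710.2 normalized counts against 21008 ± 6585, the class I heavy chain gene H2-K1 5411 ± 3507 normalized counts against 3269.9 ± 2999, and Cd274, encoding PD-L1, 481 ± 667 normalized counts against 168 ± 96.4. For B2m and Cd274 the higher mean in lines labelled WT rested largely on replicate 6, at 85138 and 1251 normalized counts. Without that library the log2 fold change of B2m was 0.20 rather than 0.83, and the log2 fold change of Cd274 was −0.67 rather than 0.56. Others moved too: Hk2 from 0.34 to 0.52, Ldha from 0.24 to 0.29, Stat3 from −0.57 to −0.04, Ifngr1 from −0.49 to −0.19, Myc from 0.47 to 0.19, Slc2a1 from 0.58 to 0.23 and H2-K1 from 0.86 to 0.37. Of the fixed genes, Rag1 was the 1 that passed when adjusted over the list alone.

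For the 8 gene lists that passed the set test, the inter-gene correlation estimated from the data was 0.36 to 0.81. The preset value was 0.01, so the preset test treated members as more independent than they were. With the estimated correlation 0 lists passed. Higher or lower below therefore describes the direction of most members in these lines. Among gene lists, targets of the growth-promoting transcription factor MYC were higher in lines labelled WT. Of the 57 members 51 had a positive log2 fold change, with a median of 0.35, or 1.28-fold, and the list passed the set test (camera, adjusted p = 4.67e-07; adjusted p = 0.796 with an estimated correlation). Gnl3, which encodes the nucleolar protein nucleostemin, had 5258 ± 1073 normalized counts against 3143 ± 299. Fbl, encoding the ribosomal RNA methyltransferase fibrillarin, had 5545 ± 2077 normalized counts against 3001 ± 649, and the tRNA exporter gene Xpot 16985 ± 3029 normalized counts against 11400.0 ± 1505. By library the list's mean log2 level was 11.8, 11.5 and 12.2 in WT replicates 2, 4 and 6 and 11.7, 11.3 and 11.5 in Rag1KO replicates 1, 3 and 7, so the groups overlapped. WT replicate 6 lay above every other library for 36 of the 57 members. Without that library the median was 0.16 (adjusted p = 0.00418; 0.980 with an estimated correlation), and Fbl went from 0.85 to 0.56 on the log2 scale.

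Respiratory chain genes of the mitochondrial genome were lower in lines labelled WT. Of 13 members 12 had a negative log2 fold change, with a median of −0.35 (camera, adjusted p = 0.0286; adjusted p = 0.796 with an estimated correlation). mt-Nd5 had 51694 ± 16006 normalized counts against 70537 ± 11429 and mt-Nd6 336 ± 114 normalized counts against 595 ± 18.0, and mt-Nd5 went from −0.49 to −0.23 on the log2 scale without WT replicate 6. All 13 were lowest in WT replicate 6, where mitochondrially encoded genes took 0.917% of the reads against 1.45% to 2.03% in the other 5 libraries. Without it the median was −0.01 (adjusted p = 0.968), and the list also missed the threshold without Rag1KO replicate 1 (adjusted p = 0.352) or 3 (0.0547). The nuclear-encoded respiratory chain genes did not pass with all 6 libraries (median 0.08, 51 of 76 positive, adjusted p = 0.166). They passed without WT replicate 6, with a median of 0.15 (adjusted p = 0.00231; 0.764 with an estimated correlation). The complex III gene Uqcrc2 had 5706 ± 982 normalized counts against 3872 ± 598 and the complex I gene Ndufab1 1987 ± 311 normalized counts against 1379 ± 203.

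The other metabolic lists did not pass with all 6 libraries. TCA cycle genes had a median of 0.06 (adjusted p = 0.246), and passed without WT replicate 6 with a median of 0.17 (adjusted p = 0.0208; 0.764 with an estimated correlation). Suclg2, a subunit of succinyl-CoA ligase, had 5221 ± 219 normalized counts against 3315 ± 528. Glycolysis genes had a median of 0.19 but a mean of −0.20, with an adjusted p of 0.814. Their members Slc2a3 and Pfkfb4 were 4.39-fold and 3.6-fold higher in lines labelled Rag1KO without passing. Slc2a3 went from −2.13 to −1.26 and Pfkfb4 from −1.85 to −1.09 on the log2 scale without WT replicate 6. The median was 0.25 for pentose phosphate and nucleotide synthesis (adjusted p = 0.0635), where Taldo1 and Paics were 1.59-fold and 1.54-fold higher in lines labelled WT, and 0.33 for serine and one-carbon metabolism (adjusted p = 0.0648), where Psph and Shmt2 were 1.67-fold and 1.64-fold higher. The first of these lists passed without Rag1KO replicate 1 (adjusted p = 0.00193) or WT replicate 4 (0.00995), and the second without Rag1KO replicate 7 (0.00382) or WT replicate 4 (0.0063). With an estimated correlation these adjusted p values were 0.999 and 0.720 for the first and 0.862 and 0.720 for the second. Leaving out WT replicate 6 took the medians to 0.04 and 0.17, and Psph went from 0.74 to 0.40 and Shmt2 from 0.71 to 0.34. Amino acid transport and glutamine metabolism had a median of 0.16 and a mean of −0.18 (adjusted p = 0.688). Its member Slc38a1, a glutamine transporter gene, was at 13.5 and 24.6 normalized counts in WT replicates 4 and 6 and between 1109 and 2118 in the other 4 lines, and Got2 was at 12849.6 ± 1022 normalized counts against 9887 ± 2566. Slc38a1 went from −4.35 to −3.52 without WT replicate 6, and the list's median to −0.01. Fatty acid oxidation had a median of −0.18 (adjusted p = 0.265; without WT replicate 4 0.0314, or 0.720 with an estimated correlation), with Echs1 1.58-fold higher and Cpt1c 1.58-fold lower in lines labelled WT. Its median was −0.01 without WT replicate 6.

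Cholesterol and fatty acid synthesis genes changed side with 1 library. With all 6 libraries 22 of 27 members were lower in lines labelled WT, with a median of −0.37 (adjusted p = 0.192), and Srebf1, a master regulator of the pathway, had 5144 ± 981 normalized counts against 6823 ± 1953. Without WT replicate 6, which lay below every other library for 24 of the 27, the median was 0.38 and the list passed in the opposite direction (adjusted p = 0.000834; 0.980 with an estimated correlation). Srebf1 went from −0.39 to −0.24. The list passed on the first side without Rag1KO replicate 3 (0.0112), WT replicate 2 (0.0279) or WT replicate 4 (0.00289), with adjusted p = 0.928, 0.850 and 0.720 with an estimated correlation.

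Interferon response genes were higher in lines labelled WT, with 43 of 45 tested members positive and a median of 0.92, or 1.9-fold (camera, adjusted p = 0.000678; adjusted p = 0.796 with an estimated correlation). Ifit3, an antiviral effector, had 16221 ± 19310.0 normalized counts against 4418 ± 4072, and the immunity-related GTPase gene Tgtp1 989 ± 1094 normalized counts against 204 ± 249. WT replicate 6 was the highest library for 39 of the 45, and Rag1KO replicate 3 had the lowest mean log2 level, 6.56, against 8.86 to 12.0 in the other 5 libraries. WT replicates 2 and 4, at 9.09 and 8.86, lay below Rag1KO replicates 1 and 7, at 9.22 and 10.6, and 0 of the 45 members had separated groups. Without WT replicate 6 the median was 0.07 (adjusted p = 0.912), and without Rag1KO replicate 3 the adjusted p was 0.911. Ifit3 went from 1.90 to 0.89 and Tgtp1 from 2.44 to 1.56 on the log2 scale without WT replicate 6. MHC class I antigen presentation genes were also higher in lines labelled WT, 15 of 22 being positive with a median of 0.39 (camera, adjusted p = 0.0281; adjusted p = 0.796 with an estimated correlation). The non-classical class I gene H2-T23 had 7094 ± 3500.1 normalized counts against 1971 ± 952 and H2-T22 5428 ± 786 normalized counts against 3693 ± 960.5. Replicate 6 exceeded every other library for 16 of the 22 members, and without it the median was 0.05 (adjusted p = 0.850). The adjusted p was 0.157 without Rag1KO replicate 1 and 0.107 without Rag1KO replicate 3.

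The remaining immune lists did not pass. All 4 tested genes of MHC class II presentation, too few for a set test, had a negative log2 fold change, with a median of −2.72. For Cd74, the invariant chain gene, the mean of normalized counts went the other way, at 82.8 ± 137 normalized counts against 72.0 ± 77.3. WT replicate 6 was the lowest library for all 4, and without it the median was −1.52. Among its members, H2-DMb1, a peptide-editing chaperone subunit gene, was at 87.0 ± 104 normalized counts against 707 ± 322 and H2-DMb2 at 7.47 ± 8.94 normalized counts against 59.1 ± 27.6. Cd74 went from −1.92 to −0.10, H2-DMb1 from −4.53 to −2.58 and H2-DMb2 from −3.53 to −2.40 on the log2 scale without WT replicate 6. Immune checkpoint and ligand genes had a median of −0.22 (adjusted p = 0.476), or 0.03 without WT replicate 6. Fas, the death receptor gene, had 128 ± 116 normalized counts against 409 ± 83.8 and the galectin gene Lgals3 23373 ± 7704 normalized counts against 10047 ± 5712. Chemokines and cytokines had a median of −0.87 (adjusted p = 0.265), or −0.35 without that library, with Cx3cl1, encoding the chemokine fractalkine, at 4345 ± 2591 normalized counts against 1389 ± 271 and Csf1, the macrophage growth factor gene, at 29348 ± 12994 normalized counts against 58302 ± 16145. Csf1 went from −1.06 to −0.65 on the log2 scale without WT replicate 6. The JAK-STAT3 list had a median of −0.08 (adjusted p = 0.382), or 0.00 without that library, and its member Pias3, an inhibitor of STAT3, was 1.51-fold higher in lines labelled Rag1KO.

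Proliferation genes were lower in lines labelled WT, 23 of 35 being negative with a median of −0.24 (camera, adjusted p = 0.0286; adjusted p = 0.796 with an estimated correlation). The mitotic genes Cdc20, Kif20a and Cenpa were 1.53-fold, 1.77-fold and 1.73-fold higher in lines labelled Rag1KO, with the groups separated. They were picked by lowest p, which favours separated groups. Of the 35 members 4 were separated, all higher in lines labelled Rag1KO, where 12.1% of all genes tested were separated. Without WT replicate 6 the median was −0.32 (adjusted p = 0.000269; 0.980 with an estimated correlation). Without Rag1KO replicate 1 the test lay on the other side of 0 (adjusted p = 0.998), and the list missed the threshold without Rag1KO replicate 7 (0.183), WT replicate 2 (0.0647) or WT replicate 4 (0.869). Unfolded protein and integrated stress response genes were higher in lines labelled WT (20 of 26 positive, median 0.27, camera adjusted p = 0.0103; adjusted p = 0.796 with an estimated correlation). The stress transcription factor genes Atf4 and Ddit3 had 21489 ± 5854 normalized counts against 14762 ± 1872 and 5749 ± 2663 normalized counts against 2918 ± 636. WT replicate 6 was highest for 19 of the 26, and without it the median was 0.08 (adjusted p = 0.540), and Atf4 went from 0.52 to 0.30 and Ddit3 from 0.90 to 0.55. Without Rag1KO replicate 1 the adjusted p was 0.157.

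Extracellular matrix and mesenchymal genes were lower in lines labelled WT, 27 of 34 being negative with a median of −0.77, or 1.7-fold (camera, adjusted p = 0.0286; adjusted p = 0.796 with an estimated correlation). The collagen gene Col5a2 had 91954 ± 59677 normalized counts against 245663 ± 86116 and Snai1, a regulator of mesenchymal transition, 1448 ± 642 normalized counts against 3000.4 ± 1383. Pericyte and smooth muscle markers were lower as well, 10 of 12 being negative with a median of −2.86 (camera, adjusted p = 0.00972; adjusted p = 0.796 with an estimated correlation), Mcam having 83.0 ± 112 normalized counts against 1057 ± 894 and Myh11 39.8 ± 63.3 normalized counts against 441 ± 635. WT replicate 6 was the lowest library for 23 of the 34 matrix genes and 9 of the 12 pericyte markers. Without it the medians were 0.00 (adjusted p = 0.810) and −0.55 (adjusted p = 0.333), and without Rag1KO replicate 3 the adjusted p was 0.586 and 0.074. Col5a2 went from −1.72 to −0.91, Snai1 from −1.06 to −0.70, Mcam from −4.14 to −3.32 and Myh11 from −3.87 to −3.12 on the log2 scale without WT replicate 6.

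Lists for hypoxia, p53 and chromatin did not pass with all 6 libraries. Hypoxia response genes had a median of 0.07 (adjusted p = 0.472), or 0.20 without WT replicate 6, with Egln3 at 1834 ± 2337 normalized counts against 170.5 ± 114 and P4ha2 at 4605 ± 3065 normalized counts against 12619 ± 6117. Egln3 went from 2.67 to 1.55 and P4ha2 from −1.66 to −0.92 on the log2 scale without WT replicate 6. Targets of p53 and cell cycle inhibitors had a median of −0.30 (adjusted p = 0.192), and passed without Rag1KO replicate 7 (adjusted p = 2.26e-05; 0.510 with an estimated correlation), with Plk2 at 3279.8 ± 1130.4 normalized counts against 6186 ± 1619. Its median was −0.13 without WT replicate 6, and Plk2 went from −0.95 to −0.62. Cdkn2a, which encodes the tumour suppressors p16 and p19ARF, was at 16.4 and 97.7 normalized counts in WT replicates 4 and 6 and between 2557 and 11716 in the other 4 lines, and Cdkn2a went from −4.65 to −4.03 on the log2 scale without WT replicate 6. Chromatin and DNA methylation enzymes had a median of 0.04 (adjusted p = 0.508). Kdm6a, an X-linked histone demethylase gene that escapes X inactivation, was 1.91-fold higher in lines labelled WT, and Tet1 4.75-fold lower. Tet1 went from −2.25 to −1.54 on the log2 scale without WT replicate 6.

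Markers of other cell types did not pass with all 6 libraries. Fibroblast markers had a median of −0.58 (adjusted p = 0.351). The adjusted p was 0.0166 without WT replicate 4 (0.720 with an estimated correlation), and without WT replicate 6 the median lay on the other side of 0, at 0.21 (adjusted p = 0.581). In this list Fbln1 ranged from 0.9 normalized counts in WT replicate 6 to 21303 in Rag1KO replicate 3, and Fbln1 went from −5.30 to −1.84 on the log2 scale without WT replicate 6. Neural crest and Schwann cell markers had a median of −0.95 (adjusted p = 0.462), or −0.39 without WT replicate 6, although Gfra1, a receptor for the growth factor GDNF, was higher in lines labelled WT at 5848 ± 3289.6 normalized counts against 834 ± 647 and passed when adjusted over the list alone (limma, adjusted p = 0.0434; 0.850 over all genes). Endothelial markers had a median of −0.82 and a mean of −0.05, while the test leaned towards lines labelled WT (adjusted p = 0.986), with Flt1 at 1549 ± 2255 normalized counts against 66.9 ± 54.7. Leaving out WT replicate 6 took the median to the other side of 0, at 0.08, and Flt1 went from 3.59 to 2.06. Epithelial and keratinocyte markers had a median of −1.05 (adjusted p = 0.826), Trp63 being at 17.1 ± 26.3 normalized counts against 60.7 ± 43.4. This median turned as well, to 0.39 without WT replicate 6, and Trp63 went from −2.88 to −1.56. Pan-leukocyte and macrophage markers had a median of −0.49 (adjusted p = 0.265), with Csf1r at 115 ± 137 normalized counts against 244 ± 160.0 and Lyz2 at 154 ± 178 normalized counts against 715 ± 720.3. The melanocyte list had 4 tested members of 20, Gpnmb reaching 37519 ± 39733 normalized counts against 15694 ± 9430.4. The lymphocyte list had 2 of 20, Trac being at 40.2 ± 43.5 normalized counts against 67.0 ± 31.0. Neither was tested as a set with all 6 libraries. Of the leukocyte and macrophage markers 6 of 20 were tested, and of the epithelial and keratinocyte markers 9 of 22. Among markers chosen after their values were seen, Tyr and Tyrp1 had at most 1 read in any library. Dct and Epcam had 0 reads throughout, and Ptprc had at most 4. Without WT replicate 6 the log2 fold change was 0.01 rather than 0.87 for Gpnmb, −0.27 rather than −1.56 for Trac, −0.62 rather than −2.18 for Csf1r and −0.997 rather than −3.54 for Lyz2.

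**Figure D3:**
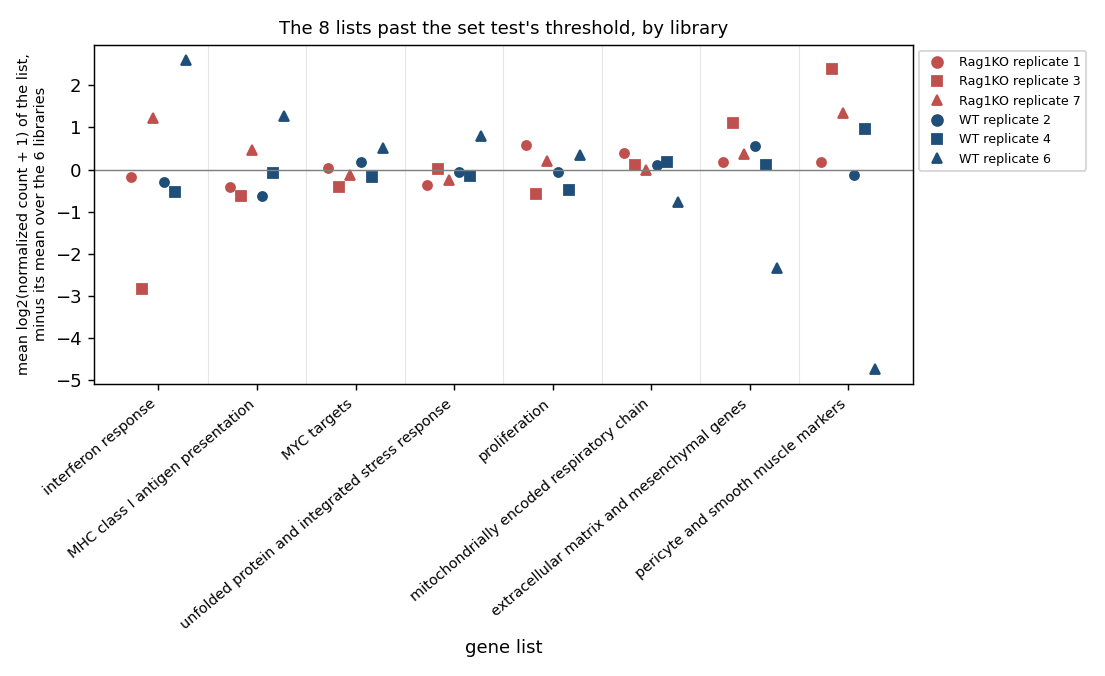
Mean log2(normalized count + 1) over the tested members of each of the 8 lists past the set test's threshold, centred on the mean of the 6 libraries, with 1 point per library. WT replicate 6 lies highest in the interferon, MHC class I, stress response and MYC lists and lowest in the mitochondrially encoded, matrix and pericyte lists, Rag1KO replicate 3 lies lowest in the interferon list, and the 2 groups overlap in all 8 lists.

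The largest difference among the lines was not between the host groups. The first principal component of log2 CPM held 53.3% of the variance and placed WT replicate 6 at 213 and the other 5 libraries between −74.2 and −28.3. Correlations across genes, which are not independent replicates, were 0.773 to 0.825 between WT replicate 6 and the other libraries and 0.908 to 0.948 among those 5. The highest, 0.948, joined Rag1KO replicate 1 and WT replicate 2. WT replicate 6 lay more than 4-fold above every other library for 250 genes and more than 4-fold below for 1196, where the other libraries had between 80 and 157 such genes in both directions together. Genes chosen after their values were seen show the size of this gap. The collagen gene Col1a1 was at 206 normalized counts in WT replicate 6 and between 478322 and 1051710 in the other 5, and the surface glycoprotein gene Thy1 at 0.9 against 29802 to 81487. Lox, a collagen cross-linking enzyme gene, was at 8.8 against 63252 to 206436. Without this library the first component held 33.6% of the variance.

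**Figure D4:**
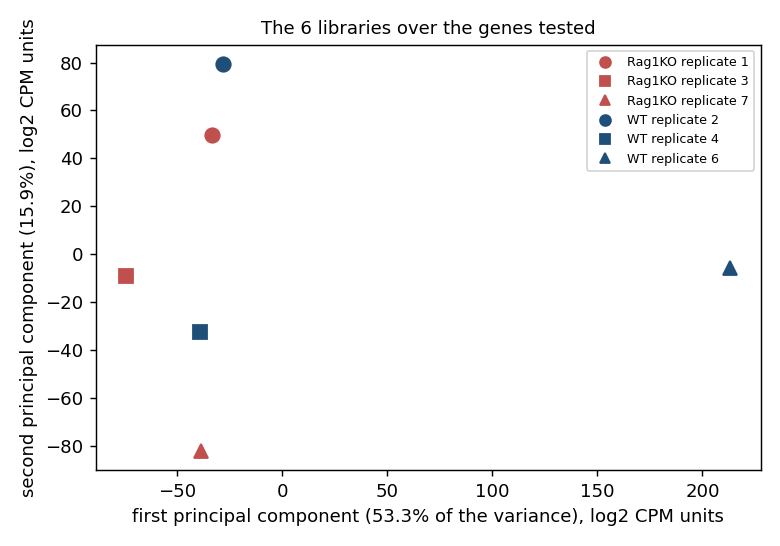
First and second principal components of log2 CPM over the 16137 genes tested, in log2 CPM units, with 1 point per library. WT replicate 6 sits at 213 on the first component, and the other 5 libraries lie between −74.2 and −28.3 with both host labels mixed.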

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

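The edgeR TMM test, planned as the main test for read counts, was made an alternative after the data were seen. The combinations that leave out WT replicate 6 and the estimated correlation with a library left out were chosen then too. So were TMM scaling, the pseudocount for lists and the components with a library left out. The limma count of 1 gene ranged from 0 to 5 with single libraries left out, the 5 coming without WT replicate 6. edgeR gave 0 with TMM and 0 with RLE, limma-voom 0 without and 0 with sample weights. Without the sex-linked list and mitochondrially encoded genes limma gave 0. DESeq2 gave 65. With inferred sex as a covariate the count was 937, where the group term compares WT replicate 6 alone with the lines labelled Rag1KO. With WT replicate 6 left out, edgeR gave 0, DESeq2 151, and limma without the sex-linked list 0. In those fits host label and inferred sex coincide and cannot be told apart. The other scalings, filters, thresholds, thinning and pseudocount gave counts within 1.5 times the original. The 8 lists past the threshold became 4 to 12 with single libraries left out, 0 with an estimated correlation, 0 with fry, and 0 with an estimated correlation whichever single library was left out. The first component held 33.6% to 61.1% of the variance with single libraries left out, the lowest without WT replicate 6. Named genes kept direction and side of the threshold in 1729 cases, lost the call in 9, gained it in 39 and reversed in 11. Lists did so in 325, 35, 14 and 2 cases, and 19 list values lay on the other side of 0 where neither test passed. With single libraries left out, the log2 fold change of Cd274 ranged from −0.67 to 1.29, the log2 fold change of Hoxc10 from −5.55 to 0.29 and the log2 fold change of Aqp1 from −0.32 to 4.09, each changing sign without WT replicate 6. The adjusted p of cholesterol and fatty acid synthesis ranged from 0.000834, in the opposite direction without WT replicate 6, to 0.717. That of proliferation ranged from 6.71e-09 to 0.998, the latter on the other side of 0 without Rag1KO replicate 1. The log2 fold change of Cd74 was 0.192 by edgeR with TMM, 0.193 with RLE and 0.194 by DESeq2, on the other side of 0. With voom sample weights the log2 fold change of Cd274 was −0.26. With sex as a covariate the log2 fold change of Ddx3y was 0.43, the log2 fold change of Kdm5d 0.49, the log2 fold change of Uty 0.44 and the log2 fold change of Hk2 −0.0337. Where fewer libraries or genes or another model term do not account for a change, the cause was not tested. No paired analysis was possible because the groups share no replicate numbers and the labels pair no lines. Scaling moved the median of all genes by under 0.1 on the log2 scale. At 55409583 to 62998051 reads per library, a count of 0 allows up to 3 reads, and thinning to the smallest library removed too few reads to test what depth limits.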

Other observations

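The tests of explanations below were chosen after the results were seen, except the counts over other splits of the libraries. The genes in this paragraph were also chosen after their values were seen. In WT replicate 6 the homeobox gene Hoxc10 was at 0 normalized counts against 2156 to 3267 in the other 5 lines, Hoxa10 at 0 against 1667 to 2834, and En1, a homeobox gene of the developing limb and brain, at 0 against 1286 to 1505. Tagln, an actin-binding protein gene of smooth muscle, was at 2.6 against 11290 to 153024. The same line had 100950 normalized counts of the water channel gene Aqp1 against 203 to 5315, 556239 of Spp1, which encodes osteopontin, against 597 to 29134, and 17438 of the interferon-induced gene Ifi44 against 1.2 to 826. Cdkn2a was low in WT replicate 4 as well as in WT replicate 6, at 16.4 and 97.7 normalized counts.

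Rag1 reads appeared in the 3 libraries labelled Rag1KO alone. Lymphocytes left in the cultures are argued against by 6 lymphocyte genes (Ptprc, Cd3d, Cd3e, Cd3g, Cd79a and Cd79b). Together these reached at most 12.2% of the Rag1 reads in any of these libraries. Trac, the lymphocyte marker named above, was not among the 6. It was detected under both labels, and its level was not set against Rag1. Higher output or copy number of the whole region is argued against too, as the 9 tested genes within 1000000 bases had a median log2 fold change of 0.0797, ranging from −2.30 to 0.86. That median does not bear on transcription at Rag1 alone. B230118H07Rik, whose coordinates cover Rag1, had a log2 fold change of −0.49 with an SE of 0.31, and reads running on from it were not tested. An exchange of the 2 group labels stays open. It cannot be told apart from transcription of an altered Rag1 allele in cells of the Rag1KO host, which may leave a partial transcript. Either could give reads in every library labelled Rag1KO and 0 libraries labelled WT with more than 3 reads. An exchange would do so only if such cells transcribe an intact Rag1, which was not tested. Reads per exon, which were not analysed here, could separate the 2 explanations.

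Eif2s3y was the 1 gene called by limma, and its absence from the lines labelled WT may have different origins. Female donors of WT replicates 2 and 4 are a candidate source there, with at most 2 reads of any Y-linked gene of the list beside abundant Xist. A female donor of WT replicate 6 is argued against by 4938 reads of Ddx3y. Loss of the stretch of chromosome Y between Kdm5d and Uty in WT replicate 6 stays open and cannot be told apart from silencing of Eif2s3y, because Gm29650, chosen after its values were seen, was the 1 other gene there with reads in all lines labelled Rag1KO and had 0 reads. An effect of the host's immune system on Eif2s3y was not tested.

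WT replicate 6 stood apart from the other 5 libraries. The authors' scaling is argued against. The highest correlation of WT replicate 6 with any library was 0.825, and a factor per library leaves a correlation of log2 values nearly unchanged. A swap with a library labelled Rag1KO would exchange labels and leave the gap to all others in place. The 0 Rag1 reads of WT replicate 6 therefore do not bear on why it stood apart. Dilution by cells of another type to one common share is argued against, since 13 abundant fibroblast markers kept a median of 17.5% of their level in the other libraries but ranged from 0.00197% to 103%. The limit on that range was added after the shares were seen, as was a bound that argues against cells like those of the other cultures making up 1% or more, with 4 markers below 1% and the lowest at 0.00197%. A line of another origin, a sample from outside the series and an effect of the host in that line alone remain open, and WT replicates 2 and 4 give no test of the last.

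With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In limma, 1 of the 10 splits, the real split, gave at least 1 gene, and the highest other count was 0. In DESeq2, 5 of the 10 splits gave at least the real count of 65, the highest other being 684, for Rag1KO replicates 1 and 3 with WT replicate 2 against the rest, which points to a structure of the samples or to over-calling by DESeq2 at this spread, neither of which was tested. For that split limma called 0 genes, and 6 lists passed. For lists, 5 of the 10 splits gave at least the real count of 8, the highest other being 16.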
